A study of Mus musculus with 10 samples.

How the data were processed

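Total RNA was taken from splenocytes of 6-week-old FVB mice, copied into cDNA labelled with 32P and hybridised to mouse cDNA membranes, per the labels' protocols. The deposited spot values are intensity values: per the file headers, each is the mean grey level of a spot and of a ring of local background around it, read by automatic segmentation from an inverted image and not normalized. The exposure, the linearity of the image and the meaning of the spot codes 0 and 2 are not given in the sources used here. Spots of code 0 had a median signal above background of 18.2 grey levels and spots of code 2 of 2.88, so a gene was taken as above background on an array when at least 1 of its 2 spots had code 0. The authors also deposited 1 table of processed values, taken here as log2 from their range. Medians per array ran from -2.71 to -1.18, with many values tied at each array's minimum. The lowest medians, -2.37 and -2.71, were those of transgenic replicates 6 and 7, with 221 and 247 of 588 values at the minimum. On the other arrays 109 to 131 values lay there. How the processed values were scaled, centred and floored is not given in the sources used here. The entries also carry no gene names that could be matched, so the table served only for counts of genes.

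Gene names were those printed in the files. They were matched by hand to current mouse symbols, of which 547 of 597 were given one, and the other 50 kept the name in the file; the RefSeq gene table of the assembly GRCm38.p6 was used only for symbols, and no coordinates were taken from it. The spots without a gene name, 126 on each array, were left out of normalization and tests but used in fitting the background.

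Background was corrected with the normexp method and an offset of 50 grey levels, arrays were quantile normalized over the gene spots, and the duplicate spots of a gene were averaged on the log2 scale. The groups were compared over all 597 genes with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no filter on dim genes. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Cd22 was also tested by a two-sided exact permutation test over the 120 splits of the 10 arrays into 7 and 3.

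Of 27 gene lists written from general knowledge before the data were examined, the 22 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation, with fry and with an exact permutation test of the list mean. The rule for the genes named in the text was also fixed before the data were examined. It took Cd22, then the genes past the threshold with the largest changes, filled up to 5 in each direction with the smallest unadjusted p and each said not to have passed, then from each list described the 3 members with the smallest p, and the housekeeping genes as a group. Not every gene that the rule allowed is named, and some items are not reported here; Pax5 and Blk were added so that all 5 members of the B cell list are given, after their values were seen.

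Times in the file headers placed transgenic replicates 6 and 7 in a second sitting of image quantification. The sitting was added as a block, and the comparison was repeated within the first sitting (5 transgenic and 3 wild-type arrays). Since the second sitting held no wild-type array, both take the difference from first-sitting arrays alone and are not separate checks. The alternatives were other normalizations (median centring, cyclic loess, centring on the housekeeping genes), other background corrections (none, subtraction with a floor at the 5th percentile, offsets of 0 and 200), filters on dim genes, array weights, a trended robust prior, the authors' processed values, leaving out each array, and either number series of the transgenic mice alone. A single background value per array, leaving out spots with local background above 100 grey levels, leaving out spots of code 2, the B cell list without Cd22 or Pax5 or with flooded spots left out and lists of 4 allowed, the other list tests of the oncogenes without wild-type replicate 3, and the first-sitting values of unnormalized Cd22 signal and of unnamed spots were chosen after seeing the data.

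The steps were tested, first after an exploration of the real arrays, on simulated data in 20 runs over 597 genes for the comparison of transgenic with wild type. These data were built from the levels of the wild-type arrays and the spread and local background of all 10 arrays. The genes changed were drawn from the 357 that were above background on all 10 arrays, so the shares called do not cover dimmer genes. Of 400 genes changed at each size, 3% were called at 1.2-fold, 15.5% at 1.5-fold, 43.5% at 2-fold and 82% at 4-fold; the 4-fold size was added after a first run with the 3 smaller sizes. A 2-fold change was seen as 0.30 on the log2 scale where 1 was put in, on the scale with the offset. False calls were 63 of 639 calls, or 9.86%, above the nominal 5%. The simulation added the spread of duplicate spots to a spread between arrays that already contained it, so its noise is larger than that of the data. The list of B cell markers was called in 0 of 20 runs with no change, 7 of 20 with a 1.2-fold fall and 20 of 20 with a 1.5-fold fall. The simulated genes varied independently of each other, whereas these markers had an estimated correlation of 0.25 in the real arrays. These runs therefore do not show how often the list test calls falsely in the real arrays. The number of arrays limits the precision of every value.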

Results

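The study profiled RNA from splenocytes, the mixed cells of the spleen, of FVB mice killed at 6 weeks of age. It compared 7 samples from mice carrying a transgene named CD22DE12 with 3 samples from wild-type mice. CD22 is a surface co-receptor of B cells that dampens signalling through the B cell receptor, and CD22DE12 is known as a form of CD22 that lacks an exon and was described in B-precursor leukaemia. Each sample was hybridised as 32P-labelled cDNA to its own nylon membrane, on which 597 named genes were spotted in duplicate, 588 on the main field and 9 as housekeeping genes. The titles carry animal-like numbers, but nothing states that every array came from a separate mouse, so the p-values measure the spread between these samples. Between 463 and 550 of the 597 genes stood above background on an array, counting a gene when at least 1 of its 2 spots had the code 0. Transgenic replicates 6 and 7 were quantified in a second sitting, which held no wild-type array, and their median signal above background was 4.45 and 4.06 grey levels against 13.8 to 18.7 on the other 8 arrays. Differences are log2 values, transgenic minus wild type, on a scale with 50 grey levels added to each signal. This understates changes at all signal levels seen here, and those of dim genes most. In the simulated data a 2-fold change, 1 on the log2 scale, was seen as 0.30.

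Cd22 itself was read first, as the gene of the transgene. Its normalized signal was 6.66 ± 0.13 (SD, n = 7) in transgenic and 6.90 ± 0.16 (SD, n = 3) in wild-type splenocytes, a difference of -0.24 with a standard error of 0.087 and a 95% interval of -0.43 to -0.05. Before normalization the Cd22 spots lay 55.1 ± 19.2 grey levels (SD, n = 7) above their local background in the transgenic group and 74.1 ± 6.60 (SD, n = 3) in the wild-type group; without the dimmer arrays of the second sitting the transgenic value was 63.3 ± 14.4 (SD, n = 5). In normalized signal all 7 transgenic arrays lay below the wild-type mean, although the groups overlapped, and by the spot code Cd22 was above background on all 10 arrays. The difference did not pass: limma gave an unadjusted p of 0.0183 and an adjusted p of 0.562, and the two-sided exact permutation test gave p = 0.05, with 6 of 120 splits as large and 0.00833 as the smallest p the design allows. With the sitting as a block, which also rests on first-sitting arrays alone, the difference was -0.26. Among the 8 arrays of the first sitting, normalized anew, it was -0.25 (exact permutation p = 0.107, n = 5 and 3). With no offset it was -0.46, and the labels state neither the species of the transgene nor the part of Cd22 that the membrane carries, so this value does not check the genotypes.

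The question put to all genes was which of them differed in level between transgenic and wild-type splenocytes. No gene passed: limma with Benjamini-Hochberg adjustment called 0 of 597 genes, and the smallest adjusted p was 0.503. At an unadjusted p under 0.05 there were 43 genes, 14 higher and 29 lower in the transgenic group, where 29.85 were expected by chance. The exact permutation test per gene called 29 at an unadjusted p under 0.05 and 0 after adjustment (smallest adjusted p 0.765). Its smallest possible p is 0.00833, so over 597 genes it could call any only if very many stood near that floor. With a minimum change of 1.5-fold, or 0.585 on the log2 scale, limma also called 0. The largest difference in size of any gene was 0.52 on the scale with the offset, so that test could call none. Neither 0 is separate support for an absence of changes. In 10 genes the groups did not overlap, 3 higher and 7 lower in the transgenic group, and chance gives 9.95. The median 95% interval of a gene reached 0.11 to either side of its estimate on the log2 scale with the offset.

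Among the genes higher in transgenic splenocytes, the smallest unadjusted p belonged to Prkca, the alpha form of protein kinase C, at 0.16 with a standard error of 0.037 and an adjusted p of 0.503 by limma. Next came Dnajc3, a co-chaperone of the endoplasmic reticulum, at 0.16 (0.09 without wild-type replicate 2), the myosin light chain gene Myl6 at 0.32, the 14-3-3 gene Ywhah at 0.19 and the homeobox gene Hoxd4 at 0.11, each with an adjusted p of 0.562. Among the genes lower in transgenic splenocytes, Apc, a negative regulator of beta-catenin, stood at -0.28 with a standard error of 0.072, the interferon gamma receptor chain Ifngr2 at -0.23, the transcription factor Ets2 at -0.09 and the chromatin organiser Satb1 at -0.17, each with an adjusted p of 0.562. Every one of the 7 transgenic arrays lay on the same side of the wild-type mean for 8 of these 9 genes, and 6 of 7 did for Myl6. The genes were taken for their small p in these same arrays, so this agreement is no separate support. Ets2 was above background on 6 of the 7 transgenic and all 3 wild-type arrays, and its sign turned with arrays centred on the housekeeping genes. The sizes given for these genes depend on the offset. With none, Prkca stood at 0.96, Hoxd4 at 0.83, Apc at -0.96 and Ets2 at -0.90, but Dnajc3 at 0.25 and Satb1 at -0.28. Of the 71 genes taken by the naming rule, 36 had a difference that moved by over 1.5 times when 1 array was left out, 33 of them when a wild-type array was, and 1, Bcl2, turned sign.

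B cell markers were the gene list that passed. Of 25 markers written down, 5 were on the membrane, and all 5 were lower in transgenic splenocytes, with a mean difference of -0.13 and a median of -0.13. The list mean was 6.51 ± 0.08 (SD, n = 7) in transgenic and 6.64 ± 0.12 (SD, n = 3) in wild-type arrays, and all 7 transgenic arrays lay below the wild-type mean. The camera test with a preset correlation of 0.01 gave an adjusted p of 0.0120 over the 22 lists. The call was lost with an estimated correlation, at an adjusted p of 0.797, with fry at an adjusted p of 0.503, and in the two-sided exact permutation test of the list mean at p = 0.0667, where 8 of 120 splits were as large. Besides Cd22, the members were Pou2af1, a co-activator of octamer-dependent transcription in B cells, at -0.14, the costimulatory receptor Cd40 at -0.13 (-0.16 to -0.08 leaving out 1 array), the B lineage transcription factor Pax5 at -0.10 and the Src family kinase Blk at -0.07. Pou2af1, Cd22 and Cd40 passed when adjusted over the list alone, each at 0.0340 by limma, and 0 of the 5 passed over all genes. Local background at Pax5 exceeded 100 grey levels on all 10 arrays, so that its level is unreliable; without Pax5 the adjusted p of the list was 0.0102. With the sitting as a block the list's mean difference was -0.16 and its adjusted p 0.0129, and within the first sitting these were -0.16 and 0.0213. Both take the difference from first-sitting arrays alone, so they are not separate checks. With arrays centred on the housekeeping genes the mean difference was -0.02, 3 of the 5 members were lower and the exact permutation p of the list mean was 0.875. Camera, which sets the list against all genes, still called it there (unadjusted p = 0.00151), since the median of all genes moved to 0.10. Without wild-type replicate 3 the mean difference was -0.08 with 3 of 5 lower and an adjusted p of 0.221, and without wild-type replicate 1 the adjusted p was 0.0573. Without Cd22 the adjusted p was 0.124, and the call was also lost under several other settings given with the processing alternatives.

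**Figure D1:**
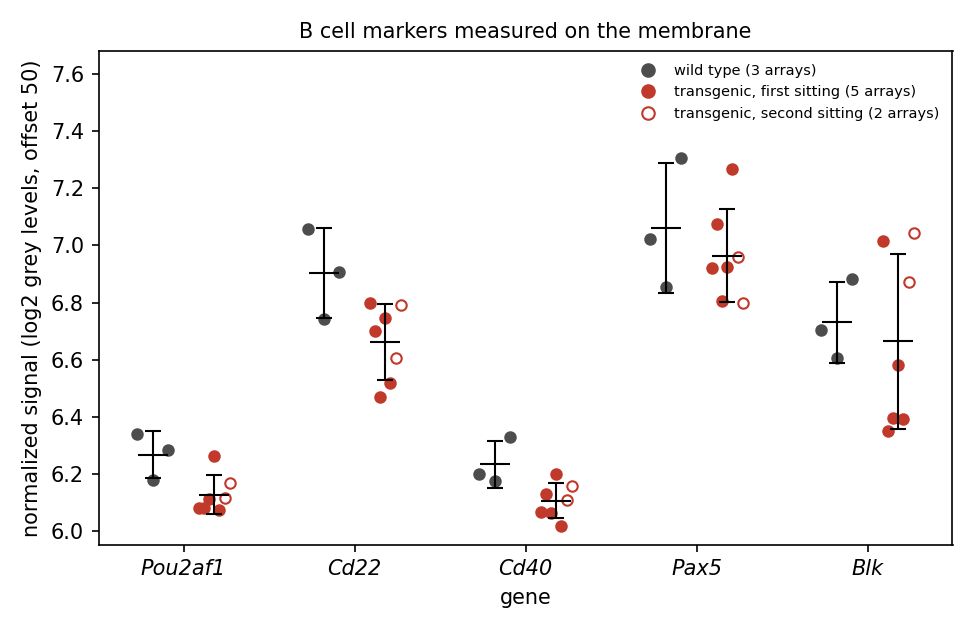
Normalized signal (vertical axis, log2 grey levels with an offset of 50) of the 5 B cell markers on the membrane (horizontal axis), 1 point per array, with the mean and SD of each group as bars; open points are the 2 transgenic arrays of the second sitting. Cd22 averaged 6.66 in the transgenic and 6.90 in the wild-type arrays, all 5 genes had lower transgenic means, and the groups overlapped in each.

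Other lists of the B lineage did not pass. Early B precursor genes had a mean difference of -0.03 over 8 measured genes, 6 of them lower (adjusted p = 0.71 by limma camera), with Ebf1, a transcription factor that specifies B cells, at -0.10 and the interleukin 7 receptor gene Il7r at -0.08 (-0.14 to -0.01 leaving out 1 array). B cell receptor signalling had a mean of -0.05 over 11 genes, 7 of them lower (adjusted p = 0.615), with the ubiquitin ligase Cbl at -0.11 and the kinase Fyn at -0.09. That list shares Cd22 and Blk with the B cell markers. Plasma cell genes had 0 members on the membrane.

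Markers of other spleen cells were tested the same way. T cell markers had a mean difference of -0.03 over 10 genes, 7 of them lower (adjusted p = 0.655), with the T cell kinase Lck at -0.18 and the adhesion molecule Cd2 at -0.14. Myeloid and granulocyte markers had a mean of 0.03 over 12 genes, 7 of them higher (adjusted p = 0.615), with the GM-CSF receptor chain Csf2ra at 0.12, the integrin Itgam at 0.11 (0.03 to 0.21 leaving out 1 array) and the lipopolysaccharide co-receptor Cd14 at 0.15. Stromal and endothelial genes had a mean of -0.002 over 11 genes, 7 of them lower (adjusted p = 0.808), with the endothelial adhesion molecule Pecam1 at -0.14. The direction of the T cell list turned in 1 of 31 alternatives, that of the myeloid list in 2 and that of the stromal list in 3. None of these genes passed over all genes or adjusted over its list alone. NK and cytotoxic cell genes (3 measured), erythroid genes (4), megakaryocyte and platelet genes (3) and the list of D cyclins with their kinases (4) fell short of the 5 measured genes needed for a test.

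Lists of growth control and transformation did not pass either. Oncogenes and leukaemia transcription factors had 13 of 17 members lower and a mean of -0.03, with an unadjusted p of 0.0390 and an adjusted p of 0.429 by limma camera. Their members with the smallest p were Ets2, Ikzf1, the lymphoid transcription factor Ikaros, at -0.13, and the tyrosine kinase Fes at -0.11. Without wild-type replicate 3 the mean of this list was -0.06 and its adjusted p 0.0167, but it was 0.182 there with an estimated correlation and 0.135 with fry, and the exact permutation p of the list mean was 0.0833. Proliferation genes had 9 of 13 members higher and a mean of 0.03 (adjusted p = 0.615), with the DNA topoisomerase Top2a at 0.23, the replication clamp Pcna at 0.09 and E2f5 at -0.10. Cell cycle inhibitors had 6 of 11 members higher (adjusted p = 0.808), with Rbl2 at 0.12 and Mdm2, which targets p53 for degradation, at -0.08. DNA repair genes had 15 of 26 members higher (adjusted p = 0.734), with Rad50 at -0.14 and Xrcc6 at 0.09. Pro-apoptotic genes had 9 of 16 members higher (adjusted p = 0.885), with Bax, an effector of mitochondrial cell death, at 0.17 and Casp4 at -0.08, and anti-apoptotic genes had 6 of 9 higher (adjusted p = 0.734), with Bag1 at 0.07 and Bcl2 at 0.11, which turned to -0.03 without wild-type replicate 1. None of these genes passed over all genes or adjusted over its list alone.

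Signalling, stress and cytokine lists did not pass. The MAP kinase cascade had 10 of 16 members higher (adjusted p = 0.734), with Mapk3 at 0.13 and Map2k1 at -0.25. JAK-STAT and cytokine signalling had 4 of 7 members higher (adjusted p = 0.734), with Irf1 at 0.10, and the NF-kB family had 4 of 7 lower (adjusted p = 0.734), with Rela at -0.17. Immediate early genes had 6 of 12 members lower (adjusted p = 0.808), with Egr1 at -0.15. Cytokine ligands had 9 of 18 members lower (adjusted p = 0.734), with Lif at -0.18, and cytokine and chemokine receptors had 15 of 24 higher (adjusted p = 0.808), with Ifngr2 lower, as given among the single genes, and Il9r at 0.15. Heat shock and stress proteins had 4 of 8 members higher (adjusted p = 0.71), with the collagen chaperone Serpinh1 at 0.23, or 0.07 without wild-type replicate 1, and the endoplasmic reticulum chaperone Hspa5 at 0.12. Nervous system genes had 5 of 8 members higher (adjusted p = 0.734), and liver and intestine genes had 5 of 7 lower (adjusted p = 0.615), with the homeobox genes Cdx2 at -0.18 and Cdx1 at -0.13. None of these genes passed over all genes or adjusted over its list alone.

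The 9 housekeeping genes of the membrane were 4 higher and 5 lower in the transgenic group, with a median of -0.08, and 0 passed. The housekeeping list fixed beforehand had 7 measured genes, 4 of them lower, and a mean of -0.09 (adjusted p = 0.734 by limma camera), led by Rps29 at -0.52 and Actb at -0.32. Without wild-type replicate 1 these were -0.22 and -0.16. Sdf4, a housekeeping gene of the membrane, went the other way at 0.35 (adjusted p = 0.606 by limma). Local background exceeded 100 grey levels at Rps29, Actb and the ubiquitin spots on all 10 arrays and at Sdf4 on 9, so their levels are unreliable. With arrays centred on the list the median of all genes moved to 0.10, and the genes at an unadjusted p under 0.05 became 36 higher and 2 lower, again with 0 past the adjusted threshold.

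Correlations between the groups overlapped those within them. Pearson correlations across genes, which are not independent replicates, ran from 0.854 to 0.947 between transgenic arrays, from 0.924 to 0.954 between wild-type arrays and from 0.886 to 0.966 between the groups. The first principal component held 28.3% of the variance and the second 17.6%. The median SD of a gene, taken as the mean of its 2 spots, was 0.08 between transgenic arrays and 0.06 between wild-type arrays. The median SD of a single spot, from duplicates on 1 array, was 0.07. A mean of 2 spots carries less spot noise than that, so these values are not directly comparable. No arrays held identical values.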

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

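The search for single arrays apart was fixed before the data were examined, and the tests of a lower B cell share and those of Cd22 in this part were chosen after the result was seen, as were the count of splits for genes past the adjusted threshold and the test of unnamed spots within the first sitting. In the transgenic group, 95 values were searched for 1 array far from the other 6, and 3 were found where chance gives about 4.75, since 1 in 20 is found with no effect. Myl6 had a normalized log2 signal of 6.34 on transgenic replicate 2, against 6.63 to 6.84 on the other transgenic arrays. Rps29 had 5.83 on transgenic replicate 4, against 5.68 to 5.72, at a spot whose local background was flooded on all 10 arrays. The mean of the liver and intestine genes was 6.14 on transgenic replicate 2, against 6.04 to 6.08. The wild-type group, with 3 arrays, was not searched. The 126 spots without a gene name differed in mean signal above background by -3.51 grey levels between transgenic and wild-type arrays (two-sided exact permutation p = 0.575), and by 1.32 within the first sitting (exact permutation p = 0.732).

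The first pattern weighed was the lower level of the B cell markers in transgenic splenocytes, at -0.13 on average. Chance cannot be excluded, since 8 of the 120 splits of the arrays gave a list difference as large in size, the highest other being 0.17. Bleed of bright spots into the local background is argued against by the list's mean difference of -0.16 with 1 background value per array; there the camera p was 0.00323, but the adjusted p rose from 0.0120 to 0.0711, while the SD of the list mean went from 0.079 to 0.089 among transgenic and from 0.12 to 0.077 among wild-type arrays and the SD of the differences over all genes, against which camera sets the list, from 0.084 to 0.11. With spots above 100 grey levels of local background left out, 4 markers remained. Their mean difference was -0.13, with an exact permutation p of 0.158. The second sitting is argued against as the whole source by the difference of -0.16 within the first sitting, where the exact permutation p was 0.0714. A lower share of B cells among the splenocytes may account for it and stays open: the shifts of myeloid and T cell markers, 0.03 and -0.03, differed with an exact permutation p of 0.0833, and an effect of the genotype on these genes was not tested apart from it.

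The second pattern was the lower Cd22 signal. The second sitting is argued against as the whole source by the difference of -0.253 within the first sitting, with a 95% interval by limma of -0.47 to -0.04. The exact permutation p there was 0.107, so chance stays open. A lower share of B cells may account for it, since Cd22 differed from the mean of the other B cell markers by -0.13 between the groups with an exact permutation p of 0.133, which leaves open whether Cd22 moved apart from them. The membrane's Cd22 fragment and the species of the transgene are not given in the sources used here, so whether the spot reads the transgene was not tested.

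The third pattern was the number of results past a threshold. For genes past the adjusted threshold the real count was 0, which all 100 of 100 splits of the 10 arrays into 7 and 3 must reach, so that count decides nothing; the highest other count was 3. For genes at an unadjusted p under 0.05, 12 of 100 splits gave at least the real count of 43, the highest other being 76. For gene lists, 40 of 100 splits gave at least the real count of 1, the highest other being 4. Chance cannot be excluded for the latter 2 counts.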

How the results depend on the processing

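In this part the runs with 1 background value per array, with spots above 100 grey levels of local background or of code 2 left out, and with the B cell list short of Cd22 or Pax5 were chosen after the result was seen. Over 37 alternatives 2769 values were compared: 2730 kept their side of the threshold, 25 lost a call, 14 gained one and 0 called values changed direction, while 82 uncalled values changed sign. The count of genes past the adjusted threshold was 0 in each alternative that gave a count, the lowest adjusted p of a named gene being 0.0667 for Myl6 with centring on the housekeeping genes; the authors' processed values gave 31 genes at an unadjusted p under 0.05, 3 higher and 28 lower, about a median shift of all values of -0.17. Ets2 turned sign in 1 alternative, to 0.003 with centring on the housekeeping genes. The Cd22 difference ran from -0.46 to -0.10. The cause of the changes below was not tested. The B cell list passed in 20 of 33 alternatives, with adjusted p from 0.000505 to 0.797. Its adjusted p was 0.0637 with no background correction, 0.108 with a floor, 0.0959 with an offset of 0 and 0.0701 with array weights. It was 0.113 with transgenic mice of 1 number series, 0.0800 with those outside it and 0.0711 with 1 background value per array. It was 0.797 with an estimated correlation, 0.503 with fry, 0.124 without Cd22 and 0.0102 without Pax5. The exact permutation test gave 0.611, but with 120 splits no list could pass alone. In the settings just named, other than those without Cd22 or Pax5, 0 lists passed. With flooded spots left out Pax5 was lost, and 0 lists passed at the minimum of 5 measured genes. With lists of 4 allowed the B cell list had an adjusted p of 0.0128 by camera, but the exact permutation p of its mean was 0.158. 2 lists passed with centring on the housekeeping genes, the B cell list and the housekeeping list, which reached 0.0220. Leaving out 1 array, the B cell list ran from 0.000505 (without wild-type replicate 2) to 0.221 (without wild-type replicate 3), losing its call also without wild-type replicate 1 at 0.0573, with 0 to 1 lists passing; the oncogene list ran from 0.0167 (without wild-type replicate 3) to 0.729 (without wild-type replicate 2). The exact permutation p of the B cell list mean and of Cd22 were 0.0417 and 0.0250 with no background correction. They were 0.142 and 0.100 with median centring, and 0.875 and 0.458 with centring on the housekeeping genes. With mice outside the number series they were 0.300 and 0.200, where 3 against 3 arrays allow no exact p under 0.05. Cd22 reached 0.0417 with cyclic loess and with an offset of 200, 0.0250 with 1 background value per array and 0.0333 without spots of code 2. Leaving out 1 array, the list ran from 0.0278 (without wild-type replicate 2) to 0.278 (without wild-type replicate 3). Cd22 ran from 0.0278 (without wild-type replicate 2) to 0.194 (without wild-type replicate 1), and was 0.0476 without transgenic replicate 1, 4 or 7. No paired analysis was possible because the labels give the groups no shared replicate numbers.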
